A study of Mus musculus with 8 samples.

How the data were processed

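RNA libraries were made by the submitters with a kit (TruSeq RNA v2) that keeps no strand information, so reads from overlapping genes on opposite strands are not separated. The mice were 8 to 14 weeks old, of mixed C57/BL6 and 129 background, and received 1 dose of 10 mg tamoxifen. The deposited table gives FPKM (fragments scaled to transcript length and to the mapped fragments of the library) per gene and library, computed by the authors. The submitters' processing notes list TopHat2 2.1.0, StringTie 1.3.4 and genome build mm9, while the annotation and any filters are not given in the sources used here. StringTie derives FPKM from read coverage, and reads that match several near-identical genes are divided or assigned among them, which makes defensin, lysozyme, globin and pseudogene values uncertain. No scaling between libraries was seen in the deposited values, whose sums ranged from 540467 to 1638347 FPKM.

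The 8 libraries were grouped by the labels into non-irradiated CD24+ (2), irradiated CD24+ (3) and irradiated CD24− (3). The table held 24015 entries for 24013 symbols. Of these 27 had date-like names left by a spreadsheet, 2 of which were repeated and summed, and 14 were tested. Genes with an FPKM of at least 1 in at least 2 libraries were kept, which left 11190. Values were transformed as log2(FPKM + 1), which pulls fold changes of genes near 1 FPKM toward 0.

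All 8 libraries were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were irradiated with non-irradiated CD24+ cells, irradiated CD24− with irradiated CD24+ cells and, as a secondary comparison, irradiated CD24− with non-irradiated CD24+ cells. No label says that replicates come from separate mice, so p-values measure only the spread between these samples. SE is the moderated standard error from limma and SD the spread of FPKM between libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

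The tests, most alternative settings and 23 gene lists with 509 entries (483 symbols, 3 of them not in the table) were fixed before the data were examined. The lists cover Paneth cell products, Paneth niche ligands, crypt base columnar and reserve stem cells, regenerative epithelium, Notch receptors and targets, Notch ligands, secretory regulators, Wnt targets, cell cycle, p53 targets, enterocyte, goblet, enteroendocrine, tuft, immune and stromal markers, the unfolded protein response, interferon-stimulated, class II antigen presentation, immediate early, cholesterol synthesis and epithelial identity genes. Each list with at least 3 measured members was tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and again with a correlation estimated from the data. Adjustment was over the 23 lists. No list passed with the estimated correlation in any comparison, so lists are described by counts of member genes. Members of a list vary together across the same libraries, so a count is not separate evidence. Adjustment over a list alone does not cover the 23 lists. Counts are to be read beside all 11190 genes, of which 5439 were called higher and 813 lower in irradiated CD24− than irradiated CD24+ cells. Against non-irradiated CD24+ cells 7349 were called higher and 558 lower.

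Named genes followed a fixed rule. It took for each comparison the 6 genes with the largest fold in each direction among called genes with at least 5 FPKM in the higher group and no overlap between groups, or the smallest p where fewer than 6 passed. It added up to 4 members of each list past the threshold, up to 2 of each other list, and 14 genes in every comparison, among them Lyz1, Notch1, Hes1 and Lgr5. Other members are named where a count is small, and these were chosen after their values were seen.

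Alternatives were another pseudocount (0.1), no filter or a filter at 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, fitting only the 2 groups compared, array weights, a robust fit, the highest entry for repeated symbols, and leaving out each library in turn. Where that left a lone library, it was assumed to vary like the other groups. Across genes the residuals of CD24+ and CD24− libraries with the same replicate number correlated at r = 0.366, 0.231 and 0.402, each the highest for its library, and genes are not independent replicates. The labels do not say that a number marks a mouse, so a block for replicate number was an alternative.

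Read numbers were not given in the sources used here. From the smallest steps between low values and transcript lengths of another annotation (GENCODE, 94.5% of symbols matched) they were approximated at 34.7 to 45.2 (in units of 1e6 reads) per library, within a factor of 1.3. The procedure was tested on simulated data with 100 genes changed at each fold. At 2-fold it recovered 36.4%, 48.0% and 36.4% of changed genes in the comparisons in the order above. At 4-fold it recovered 89.6%, 92.6% and 89.0%. False calls were 7.8, 7.6 and 5.8 per simulation. Changes were placed only in genes at higher levels, with noise independent between genes and no library standing apart. The rates therefore do not carry over to the real libraries, where genes vary together.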

Results

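Gene expression was measured by RNA sequencing in cells sorted from the intestinal epithelium of Lyz1CreER; R26R-tdT mice. In these mice tamoxifen switches on the red protein tdTomato in cells that express Lyz1, the lysozyme gene of Paneth cells, and in all of their later descendants. Paneth cells sit at the base of the crypts and secrete antimicrobial proteins. Viable epithelial cells (DAPI negative, CD45 negative, EpCAM positive) were split by the surface protein CD24, which Paneth cells carry. Tomato-positive CD24+ cells are the Paneth cell gate, and tomato-positive CD24− cells are the derivatives, that is labelled cells outside that gate. There were 2 libraries of CD24+ cells from non-irradiated mice, 3 of CD24+ cells from mice irradiated 5 days earlier and 3 of CD24− cells from irradiated mice. CD24− cells of non-irradiated mice were not analysed here, so the derivative group differs from the non-irradiated group in both gate and irradiation.

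The sort markers followed the gates, and so did Lyz1, which served for labelling and not for sorting. Lyz1 stood at 33954 ± 21126 FPKM (SD, n = 2) in non-irradiated CD24+ cells, 33888 ± 2497 (SD, n = 3) in irradiated CD24+ cells and 1258 ± 1162 (SD, n = 3) in irradiated CD24− cells. Cd24a, the gene of the sorted surface protein, stood at 642 ± 29.9, 698 ± 44.7 and 77.4 ± 39.9 FPKM in the same order. Epcam, the epithelial sort marker, was present in every group at 183 ± 60.9, 258 ± 20.05 and 669 ± 69.8 FPKM. Ptprc, which encodes the leukocyte protein CD45 that the sort removed, had group means of 0.414, 0.109 and 0.0836 FPKM, below the filter for testing. Paneth cell products (41 of 43 listed genes measured, mostly alpha-defensins) made up 60.7% ± 3.09 of all FPKM in non-irradiated CD24+ cells, 56.9% ± 0.283 in irradiated CD24+ cells and 4.55% ± 4.26 in CD24− cells. Within the CD24− group they made up 9.42% in replicate 1, 2.73% in replicate 2 and 1.498% in replicate 3. The 33 most abundant of these genes stood at a median of 7.54%, 2.08% and 1.09% of their mean level in irradiated CD24+ cells in these 3 libraries.

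**Figure D1:**
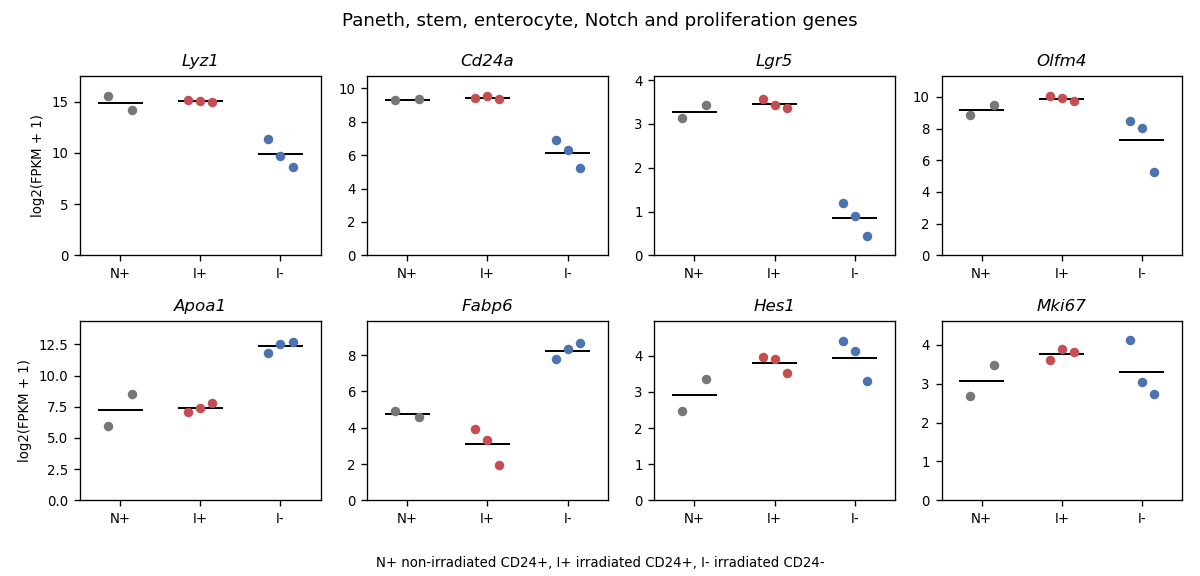
Expression of 8 genes in every library as log2(FPKM + 1), with 1 panel per gene, each library as a point and the group mean as a line, for non-irradiated CD24+ (N+, 2 libraries), irradiated CD24+ (I+, 3) and irradiated CD24− (I−, 3) cells. Lyz1, Cd24a, Lgr5 and Olfm4 are lowest and Apoa1 and Fabp6 highest in the CD24− libraries, while Hes1 and Mki67 overlap between the irradiated groups.

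The first comparison asks what differed in the Paneth cell gate 5 days after irradiation, and whether genes of Notch signalling, the cell-to-cell pathway named in the study's title, were among them. Replicate 1 of the non-irradiated group stood apart, with a median-of-ratios factor of 0.528 against 0.859 to 0.993 in the other CD24+ libraries. It had 9362 genes at 1 FPKM or more against 10293 to 10555. By approximated fragment shares, Paneth products (34 of 41 with a matched transcript length) took 69.96% of its fragments, against 51.86% to 56.45% in the others. Its fragments left for other genes were 0.667 of those in replicate 2, where the ratio of the factors was 0.609. A larger Paneth share may therefore account for much of its lower values, which was not tested. The median log2 fold change of all genes was 0.32, and it was 0.071 without this library and 0.59 without replicate 2. The fit without replicate 2, which keeps replicate 1 as the only control, called 5172 of 11156 genes higher (46.4%), so calls gained there are shared with much of the genome. Markers of tuft cells, chemosensory cells that also carry CD24 at their surface, were lower after irradiation. All 15 measured tuft genes lay below the median of all genes, and 12 of them were lower past the threshold adjusted over the list alone, against 0 over all genes. Siglec5, a sialic acid-binding receptor, stood at 1.97 ± 0.689 FPKM (SD, n = 2) without and 0.554 ± 0.158 (SD, n = 3) with irradiation, a log2 fold change of -0.92 ± 0.18 (SE). Rgs13, a regulator of G-protein signalling, went from 8.84 ± 1.58 to 3.58 ± 1.82 FPKM, and Alox5ap, which serves leukotriene synthesis, from 6.60 ± 1.03 to 2.85 ± 1.70. The limma camera test with Benjamini-Hochberg adjustment over the 23 lists put the tuft list at adjusted p = 9.01e-58, and adjusted p = 0.0662 with an estimated correlation.

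Enteroendocrine genes, which mark the hormone-producing cells, lay the other way. Of 30 measured, 28 lay above the median of all genes, and 5 were higher past the threshold adjusted over the list alone, against 0 over all genes. Cck, which encodes cholecystokinin, stood at 2.87 ± 0.131 FPKM without and 17.5 ± 0.606 with irradiation, a log2 fold change of 2.26 ± 0.42 (SE). Ghrl, the ghrelin gene, went from 32.4 ± 1.51 to 148 ± 68.8 FPKM, and Gcg, the proglucagon gene, from 7.84 ± 2.85 to 25.7 ± 8.56. The camera test gave this list adjusted p = 4.24e-05, and adjusted p = 0.609 with an estimated correlation. After scaling by medians of ratios none of its members passed over the list alone, whereas 13 tuft genes then did. Fitted with only the 2 groups compared, Cck passed over all genes (adjusted p = 0.00194). Without replicate 2 of the non-irradiated group Cck, Ghrl and Gcg passed over all genes as 46.4% of genes did (adjusted p = 0.0229, 0.0493 and 0.0280), while the direction of the list's camera test turned (adjusted p = 0.0479) although its median relative to all genes stayed positive at 0.46.

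Targets of p53, the transcription factor of the DNA damage response, were mostly above the median of all genes (19 of 28), and 2 of them were higher over the list alone, against 0 over all genes. These were Ccng1, a cyclin family member, at 17.5 ± 2.69 against 47.2 ± 8.92 FPKM, and Eda2r, a death receptor family member, at 0.278 ± 0.0215 against 2.29 ± 0.604. Eda2r passed over all genes in the fit of only the 2 groups compared (adjusted p = 0.0405), and after median-of-ratios scaling 1 p53 target was higher over the list alone. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 15.5 ± 6.18 without and 35.5 ± 8.57 FPKM with irradiation (adjusted p = 0.348). The camera test gave the p53 list adjusted p = 0.00656, and adjusted p = 0.609 with an estimated correlation, and adjusted p = 0.330 with only genes at 5 FPKM or more in 2 libraries, where its median stood at 0.00660 relative to all genes. Its direction turned without replicate 2 of the non-irradiated group (adjusted p = 0.692), where Ccng1, Eda2r and Cdkn1a each passed (adjusted p = 0.0293, 0.0274 and 0.0385). All 40 cell cycle genes lay above the median of all genes, by a median of 0.44 on the log2 scale, and limma called 0 over all genes and 0 adjusted over the list alone, with 20 at an unadjusted p under 0.05. Their median level was 4.68 and 9.33 FPKM in non-irradiated replicates 1 and 2 against 9.52, 12.3 and 15.7 in the irradiated libraries. The camera test gave cell cycle genes adjusted p = 2.53e-07, and adjusted p = 0.609 with an estimated correlation, and without replicate 1 or 2 of the non-irradiated group adjusted p = 0.000353 and 0.0662, with relative medians of 0.30 and 0.58. Mki67, a marker of proliferating cells, stood at 7.75 ± 3.34 and 12.7 ± 1.35 FPKM.

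Notch genes did not pass the test with all libraries. Hes1, a transcription factor gene switched on by Notch, stood at 6.94 ± 3.35 FPKM in non-irradiated and 13.0 ± 2.21 in irradiated CD24+ cells, a log2 fold change of 0.87 ± 0.35 (SE), or 0.54 relative to the median gene (adjusted p = 0.348). The Hes1 call rested on the control libraries: without replicate 2 of the non-irradiated group Hes1 was higher by 1.31, or 0.72 relative to the median gene of that fit (adjusted p = 0.0329), and with median-of-ratios scaling adjusted p = 0.725. Nrarp, another Notch target, stood at 2.35 ± 0.826 and 4.75 ± 1.52 FPKM, and the receptor gene Notch1 at 1.83 ± 0.824 and 2.29 ± 0.709. The ligand genes Dll1 and Dll4 had log2 fold changes of 0.16 ± 0.28 and 0.12 ± 0.24 (SE). Of 11 measured Notch receptors and targets, limma called 0 over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.818, and adjusted p = 0.987 with an estimated correlation). Of 4 ligands it called 0, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.199, and 0.00768, lower, without replicate 2 of the non-irradiated group). Among markers of crypt base columnar stem cells, Lgr5 (log2 fold change 0.17 ± 0.24), Olfm4 (0.74 ± 0.75) and Ascl2 (0.79 ± 0.43) did not pass. In that list 5 of 22 members, among them Igfbp4 (1.36 ± 0.30) and the adhesion receptor gene Cd44 (1.14 ± 0.28), were higher over the list alone, against 0 over all genes, with camera adjusted p = 0.0850, and adjusted p = 0.824 with an estimated correlation. After median-of-ratios scaling 1 member was higher and 1 lower over the list alone. The stem cell list passed without replicate 1 of the non-irradiated group (adjusted p = 0.0337) or replicate 2 or 3 of the irradiated group (0.0205 and 0.00079), with median-of-ratios scaling (0.0221) or with only genes at 5 FPKM or more in 2 libraries (0.00373). Igfbp4 and Cd44 passed over all genes without replicate 2 of the non-irradiated group (adjusted p = 0.0204 and 0.0216). Atoh1, the regulator of secretory fate, had a log2 fold change of 0.23 ± 0.35 (SE, adjusted p = 0.627).

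Several lists lay below the median of all genes in irradiated CD24+ cells. Of 41 Paneth cell products 33 lay below, with camera adjusted p = 9.85e-13, and adjusted p = 0.609 with an estimated correlation. Absorptive enterocyte markers did so in 27 of 32 (adjusted p = 3.25e-22, and adjusted p = 0.393 with an estimated correlation) and goblet markers in 13 of 21 (adjusted p = 7.15e-05, and adjusted p = 0.609 with an estimated correlation). Interferon-stimulated genes did so in 21 of 29 (adjusted p = 2.10e-06, and adjusted p = 0.609 with an estimated correlation) and unfolded protein response genes in 16 of 24 (adjusted p = 7.15e-05, and adjusted p = 0.609 with an estimated correlation). Paneth niche ligands were also called lower by camera (adjusted p = 0.000401, and adjusted p = 0.393 with an estimated correlation). Immune markers (adjusted p = 0.00656, and adjusted p = 0.393 with an estimated correlation) and immediate early genes (adjusted p = 7.57e-05, and adjusted p = 0.609 with an estimated correlation) were too. Of all these members only Gm14850, which is annotated among the defensins, and the chemokine gene Ccl9 passed over their lists alone, and both were higher; after median-of-ratios scaling 3 unfolded protein response genes and 1 immediate early gene were lower over theirs. Without replicate 1 of the non-irradiated group the calls of Paneth products (adjusted p = 0.933), niche ligands (0.103), goblet (0.0792) and immune markers (0.999) ended, and immune markers also missed the threshold without replicate 2 (0.0635) or 3 (0.0505) of the irradiated group. With median-of-ratios scaling camera no longer called Paneth products (adjusted p = 0.0503), goblet (0.0503), immune (0.907), interferon (0.907) or immediate early genes (0.161). Their relative medians were then -0.53, -0.38, 0.021, -0.12 and -0.23 in this order, against -0.43, -0.29, -0.21, -0.23 and -0.18 as deposited. Interferon genes turned higher without replicate 2 of the non-irradiated group (adjusted p = 0.0466). The 2 non-irradiated libraries differed widely in the enterocyte and interferon genes, with the enterocyte fat-transport gene Apoa1 at 61.7 and 372 FPKM and the interferon-induced Isg15 at 0.907 and 30.2 in replicates 1 and 2. The camera test did not call reserve stem cell markers (adjusted p = 0.329), regenerative genes (0.732, but 0.0254 with median-of-ratios scaling), secretory regulators (0.732), or Wnt targets (0.958, with Ccnd1 and Cd44 higher over the list alone). Nor did it call stromal markers (0.614), class II antigen presentation genes (0.283, but 0.0314 and 0.000149 without replicate 2 or 3 of the irradiated group and 0.00625 with that scaling), cholesterol synthesis genes (0.958, but 0.00269 without replicate 1 of the irradiated group) or epithelial identity genes (0.721). In the reserve, regenerative, Notch receptor, Wnt and stromal lists the median, the mean and the test did not all have the same sign.

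**Figure D2:**
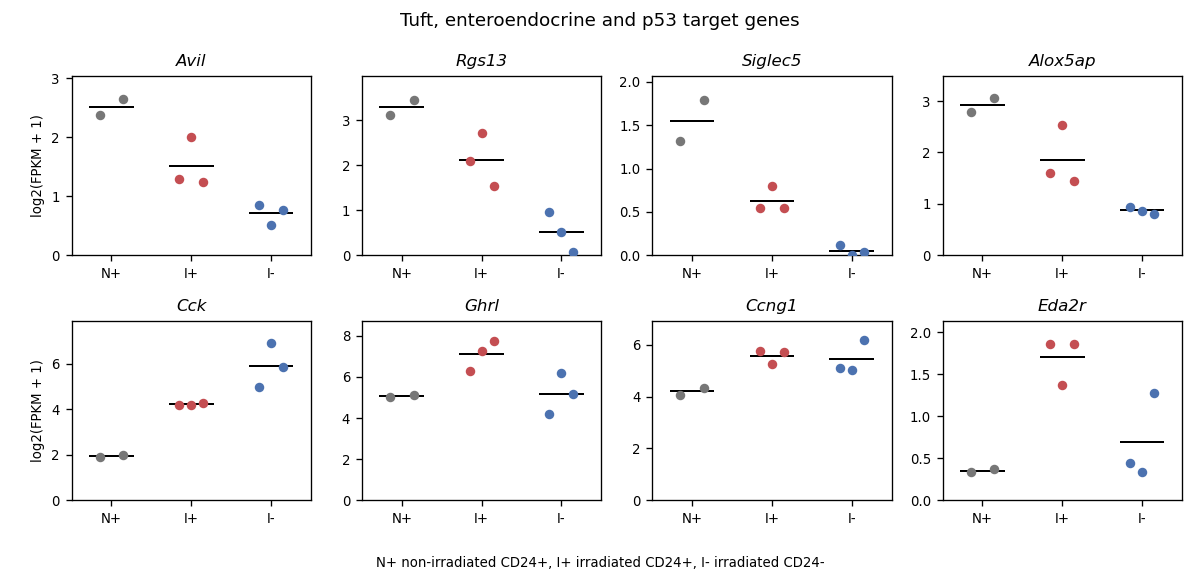
Expression of 4 tuft genes (Avil, Rgs13, Siglec5, Alox5ap), 2 enteroendocrine genes (Cck, Ghrl) and 2 p53 targets (Ccng1, Eda2r) in every library as log2(FPKM + 1), with points for libraries and lines for group means in non-irradiated CD24+ (N+, 2), irradiated CD24+ (I+, 3) and irradiated CD24− (I−, 3) cells. In CD24+ cells the tuft genes lie lower and the other 4 higher after irradiation, and none of the 8 passed the threshold over all genes in the fit of all 3 groups.

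The median log2 fold change of all genes was 0.32 here, 0.51 between the irradiated gates and 0.88 between CD24− and non-irradiated cells, and values called relative are differences from it. Over all 11190 genes, limma with Benjamini-Hochberg adjustment called 0 genes between irradiated and non-irradiated CD24+ cells, and the smallest adjusted p was 0.103. An unadjusted p under 0.05 was found for 1424 genes, 1364 higher and 60 lower, where chance gives 559.5. That count was 293 with array weights, 872 after scaling by medians of ratios, 494 and 6574 without replicate 1 or 2 of the non-irradiated group, and 1369, 470 and 493 without replicate 1, 2 or 3 of the irradiated group, so the excess over chance depends on the libraries kept. The genes with the smallest p were Cd14, a receptor for bacterial lipopolysaccharide (log2 fold change 1.29 ± 0.20), Rec8, a cohesin component (log2 fold change 1.302 ± 0.21), and the microRNA locus Mir8114 (3.27 ± 0.49). With them stood the defensin-like Gm14850 (5.37 ± 0.81, uncertain because near-identical copies share reads), Gm11545 (1.56 ± 0.25), 2210407C18Rik (2.44 ± 0.39) and, lower after irradiation, the pancreatic lipase-related Pnliprp1 (-2.15 ± 0.31). Scaling by medians of ratios called 3 genes, all lower, among them Pnliprp1 (log2 fold change -2.62, adjusted p = 0.00824) and Siglec5 (-1.27, 0.0222). The count rested on the 2 non-irradiated libraries: it was 5185 genes, 5172 of them higher, without replicate 2 and 10 without replicate 1, each time with a lone control library assumed to vary like the other groups, and 3 without replicate 3 of the irradiated group. The fit of only the 2 groups compared called 5, all higher, namely Cck, Eda2r, Mir8114, Gm14850 and 2210407C18Rik. Hbb-b1, a beta-globin gene with near-identical copies, was listed at 1.36 and 24.0 FPKM in non-irradiated replicates 1 and 2 and at 0 in the irradiated libraries.

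The second comparison sets the derivative cells against the Paneth cell gate within irradiated mice. Paneth transcripts were far lower in CD24− cells. Of 41 measured Paneth cell products, 40 fell over all genes and 40 adjusted over the list alone, with a median log2 fold change of -5.17. Lyz1 fell by 5.18 ± 0.71 (SE) on the log2 scale (adjusted p = 0.000126), and the angiogenin-family ribonuclease gene Ang4 fell by 5.14 ± 0.60. The largest falls were Defa4 (-7.72 ± 1.44), Gm15293 (-6.64 ± 0.75), Gm10104 (-5.92 ± 0.70) and Gm15315 (-5.74 ± 0.70). These belong to or are annotated beside the alpha-defensin family, whose near-identical copies share reads, as Lyz1 and Lyz2 do, so the values of single members are uncertain. Wnt3, a niche signal that Paneth cells send to stem cells, fell by 3.13 ± 0.23 (adjusted p = 5.58e-06). Bst1, listed with it among the Paneth niche ligands, rose by 4.30 ± 0.30 (adjusted p = 5.58e-06), and of the 6 measured niche ligands 2 rose and 2 fell. The limma camera test with Benjamini-Hochberg adjustment put Paneth products at adjusted p = 2.03e-46, and adjusted p = 0.286 with an estimated correlation, and niche ligands at adjusted p = 0.0544 (0.0332 without replicate 3 of CD24+ cells).

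Absorptive enterocyte genes had the highest median among the 23 lists. All 32 measured members rose, over all genes and adjusted over the list alone, with a median log2 fold change of 4.29 (camera adjusted p = 4.60e-10, and adjusted p = 0.537 with an estimated correlation). Apoa1 and Apoa4, apolipoproteins of dietary fat export, rose from 176 ± 43.0 to 5485 ± 1607 and from 204 ± 144 to 6698 ± 4663 FPKM (SD, n = 3 each). Rbp2, which binds retinol in enterocytes, rose by 4.65 ± 0.52 (SE) on the log2 scale, and Fabp6, the ileal bile acid-binding protein gene, by 5.16 ± 0.43. The barrier gene Sprr2a1, which has near-identical copies and is uncertain, rose by 4.82 ± 0.96, with 192, 231 and 1490.0 FPKM in the 3 CD24− libraries. The carboxylesterase pseudogene Ces2d-ps, which shares sequence with its family, was listed at 0 in 2 irradiated CD24+ libraries and at 0.646 FPKM in the third, against 73.0, 97.8 and 122 in CD24− cells. Among 15 epithelial identity genes 13 rose (camera adjusted p = 0.0146, and adjusted p = 0.698 with an estimated correlation, and adjusted p = 0.0635 with only genes at 5 FPKM or more in 2 libraries). They included Hnf4g, an enterocyte transcription factor (3.14 ± 0.29), Vil1, which encodes the microvillus protein villin (2.64 ± 0.31), and Epcam (1.37 ± 0.28, adjusted p = 0.00179).

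Stem cell and Wnt-dependent genes fell. Of 22 crypt base columnar markers 18 fell over all genes and 18 over the list alone, and none rose (camera adjusted p = 1.14e-17, and adjusted p = 0.286 with an estimated correlation), and all 22 fell after median-of-ratios scaling. Lgr5, the receptor that marks these stem cells, fell from 9.96 ± 0.777 to 0.833 ± 0.463 FPKM (log2 fold change -2.61 ± 0.21, adjusted p = 7.53e-06). Olfm4 fell from 954 ± 107 to 220.2 ± 166, Ascl2, a stem cell transcription factor gene, from 5.89 ± 1.98 to 1.57 ± 1.41, and Smoc2 from 53.9 ± 5.74 to 16.5 ± 10.5. Rescaled to TPM these 3 genes kept negative values and were not called (adjusted p = 0.0559, 0.109 and 0.144). In non-irradiated CD24+ cells Olfm4 already stood at 582 and Lgr5 at 8.78 FPKM (group means). Which cells of the CD24+ gate carried these transcripts was not tested, so their falls cannot be read as a change within Paneth cells. Of 18 Wnt targets 15 fell and 1 rose, both over all genes and over the list alone (camera adjusted p = 2.87e-15, and adjusted p = 0.286 with an estimated correlation). Among those that fell were the receptor kinase gene Ephb3 (-2.84 ± 0.27), the pathway inhibitor gene Nkd1 (-2.13 ± 0.18) and Bambi (-3.37 ± 0.33). Reserve stem cell markers, with 2 of 5 lower and 1 higher, gave camera adjusted p = 0.0456, and adjusted p = 0.537 with an estimated correlation. They were not called after leaving out replicate 1 (adjusted p = 0.0734) or 2 (0.0546) of CD24+ or replicate 3 of CD24− cells (0.0504), or with median-of-ratios scaling (0.117). Their relative medians were then -0.46, -0.42, -0.84 and -0.80 in this order, against -0.72 with all libraries as deposited.

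Regulators of secretory fate fell, in 8 of 15 members over all genes and 8 over the list alone, and none rose (camera adjusted p = 3.06e-08, and adjusted p = 0.313 with an estimated correlation), and 12 fell after median-of-ratios scaling. Atoh1 fell by 1.37 ± 0.31 (adjusted p = 0.00326), Spdef by 1.42 ± 0.29, Gfi1 by 1.28 ± 0.19 and Foxa3 by 1.60 ± 0.23. Rescaled to TPM, which shifts most genes upward in CD24− cells, these 4 genes kept negative values and were not called (Atoh1 -0.23, adjusted p = 0.510; Gfi1 -0.35, 0.138).

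Notch genes went both ways or did not pass. Hes1 stood at 13.0 ± 2.21 FPKM in CD24+ and 15.2 ± 5.87 in CD24− cells, a log2 fold change of 0.15 ± 0.31, or -0.36 relative to the median gene (adjusted p = 0.701). Notch1 had -0.51 ± 0.27 (adjusted p = 0.135, 0.0185 with the replicate block and 0.0424 without replicate 1 of CD24− cells). Dll1 had 0.16 ± 0.25 and Dll4 -0.38 ± 0.21 (adjusted p = 0.154). After scaling by medians of ratios Notch1 and Dll4 fell (adjusted p = 0.0174 and 0.00262), as they did with quantile normalization (0.0398 and 0.00183) and, without rescaling, with array weights (0.00831 and 0.000359). Rescaled to TPM, Hes1 (1.34, adjusted p = 0.00114), Dll1 (1.27, 0.000353) and Dll4 (0.74, 0.0112) rose instead. With the replicate block and median-of-ratios scaling together, chosen after seeing the data, Hes1 fell (-0.37, adjusted p = 0.0444). The direction of these genes thus depends on the scaling, and their rise in TPM was shared with most genes. In the list of 11 Notch receptors and targets Olfm4 and Lfng, a modifier of Notch receptors, fell and Rfng, a related modifier, and the coactivator gene Maml1 rose, the last not called without any 1 of 5 of the irradiated libraries (adjusted p from 0.0518 to 0.151). Nor was Maml1 called with no filter (adjusted p = 0.0655), quantile normalization (0.248) or median-of-ratios scaling (0.628, log2 fold change 0.085), and Lfng was not in TPM (0.216). That list gave camera adjusted p = 0.0146, and adjusted p = 0.689 with an estimated correlation, and adjusted p = 0.0527 without replicate 3 of CD24− cells. With median-of-ratios scaling 1 of its members rose and 6 fell (camera adjusted p = 0.0606). The 4 ligands gave adjusted p = 0.112.

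Of 40 cell cycle genes limma called 0 over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05. All 40 lay below the median of all genes, by a median of -0.69 on the log2 scale (camera adjusted p = 1.05e-06, and adjusted p = 0.689 with an estimated correlation). After scaling by medians of ratios 21 of them fell. Mki67 stood at 12.7 ± 1.35 FPKM in CD24+ and 9.82 ± 5.81 in CD24− cells (adjusted p = 0.261). It fell by 0.97 on the log2 scale after that scaling (adjusted p = 0.0151) or, as deposited, by 0.87 without replicate 1 of CD24− cells (adjusted p = 0.0198) or 0.69 with array weights (0.00367), and by 1.12 with quantile normalization (0.00545). Cdkn1a rose by 1.24 ± 0.37 (adjusted p = 0.0133), with 68.6, 56.0 and 153 FPKM in the CD24− libraries, and was not called after scaling by medians of ratios (0.133) or quantile normalization (0.805), or with no filter (0.0508). Of 28 p53 targets 10 rose and 2 fell over all genes and 9 rose and 2 fell over the list alone (camera adjusted p = 0.257), and 7 rose and 6 fell after median-of-ratios scaling.

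Markers of the other secretory cells went both ways. Of 21 goblet genes 5 rose and 10 fell over all genes and over the list alone (camera adjusted p = 3.40e-06, and adjusted p = 0.537 with an estimated correlation), and 2 rose and 14 fell after median-of-ratios scaling. Zg16, a mucus granule lectin, rose by 3.57 ± 0.39, while Spink4, a protease inhibitor made by goblet and Paneth cells, fell by 2.68 ± 0.49, and Ang4 and the chemokine gene Ccl6 in this list also fell. Among 15 tuft genes 11 fell and 2 rose over all genes, and 12 fell and 2 rose over the list alone (camera adjusted p = 1.51e-08, and adjusted p = 0.487 with an estimated correlation). Rgs13 fell by 1.60 ± 0.30, whereas Ltc4s, a leukotriene synthase, rose by 2.05 ± 0.25 and Plcg2, a phospholipase, by 1.34 ± 0.21. Of 30 enteroendocrine genes 4 rose and 4 fell over all genes, and 3 rose and 2 fell over the list alone. After median-of-ratios scaling 2 rose and 5 fell over all genes, and 0 rose and 5 fell over the list alone. The somatostatin gene Sst fell by 4.35 ± 0.58 and Ghrl by 1.90 ± 0.47, while the neurotensin gene Nts rose by 2.997 ± 0.73 and Cck by 1.71 ± 0.38. Ghrl was not called in TPM (adjusted p = 0.195), Nts with robust empirical Bayes (0.0552) or Cck with quantile normalization (0.170). Their camera value was adjusted p = 0.0263, and adjusted p = 0.776 with an estimated correlation. The call ended with the replicate block (adjusted p = 0.228), with median-of-ratios scaling (0.306), without replicate 1 of CD24− cells (0.95) or without replicate 2 (0.0664) or 3 (0.131) of CD24+ cells.

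Interferon-stimulated genes were higher in CD24− cells. Of 29 measured 24 rose over all genes and 24 over the list alone, and none fell; after median-of-ratios scaling 15 rose over all genes and 19 over the list alone. Ifit1 rose by 3.61 ± 0.79 (SE) on the log2 scale, Isg15, a ubiquitin-like modifier, by 3.51 ± 0.81, Ddx60, a helicase, by 2.62 ± 0.52 and Oasl2 by 2.57 ± 0.69, the last not called with quantile normalization (adjusted p = 0.0900) or robust empirical Bayes (0.0647). The camera test gave adjusted p = 0.0459, and adjusted p = 0.776 with an estimated correlation, and adjusted p = 0.0929 without replicate 3 of CD24− cells. It was also not called with pseudocount 0.1 (adjusted p = 0.0812) or with only genes at 5 FPKM or more in 2 libraries (0.0793). Cholesterol synthesis genes rose in 16 of 19 members over all genes and 19 over the list alone, with camera adjusted p = 0.0544. After median-of-ratios scaling 6 rose over all genes and 6 over the list alone (camera adjusted p = 0.0290). As deposited the camera adjusted p was 0.00772 with the replicate block and 0.00738 without replicate 3 of CD24+ cells. It was 0.0346 or 0.0438 without replicate 1 or 2 of CD24− cells. With an estimated correlation camera gave this list adjusted p = 0.776 as deposited and 0.728 with that scaling. Of 24 unfolded protein and stress response genes 2 rose and 4 fell over all genes and over the list alone (camera adjusted p = 0.000382, and adjusted p = 0.612 with an estimated correlation). After median-of-ratios scaling 0 rose and 16 fell over all genes. Ern2, an endoplasmic reticulum stress sensor of mucus-producing cells (-1.68 ± 0.28), and Asns, asparagine synthetase (-1.17 ± 0.20), were among those that fell, but were not called in TPM (adjusted p = 0.115 and 0.796). The camera test did not call regenerative genes (adjusted p = 0.711; 5 of 14 rose), or immediate early genes (0.593; 9 of 17 rose, and after median-of-ratios scaling 7 rose and 2 fell). Nor did it call class II antigen presentation genes (0.373), immune markers (0.598, with Lyz2 lower and Itgam higher, and a median of the opposite sign to the test) or stromal markers (0.711; 2 of 3 rose, and 0 after that scaling).

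**Figure D3:**
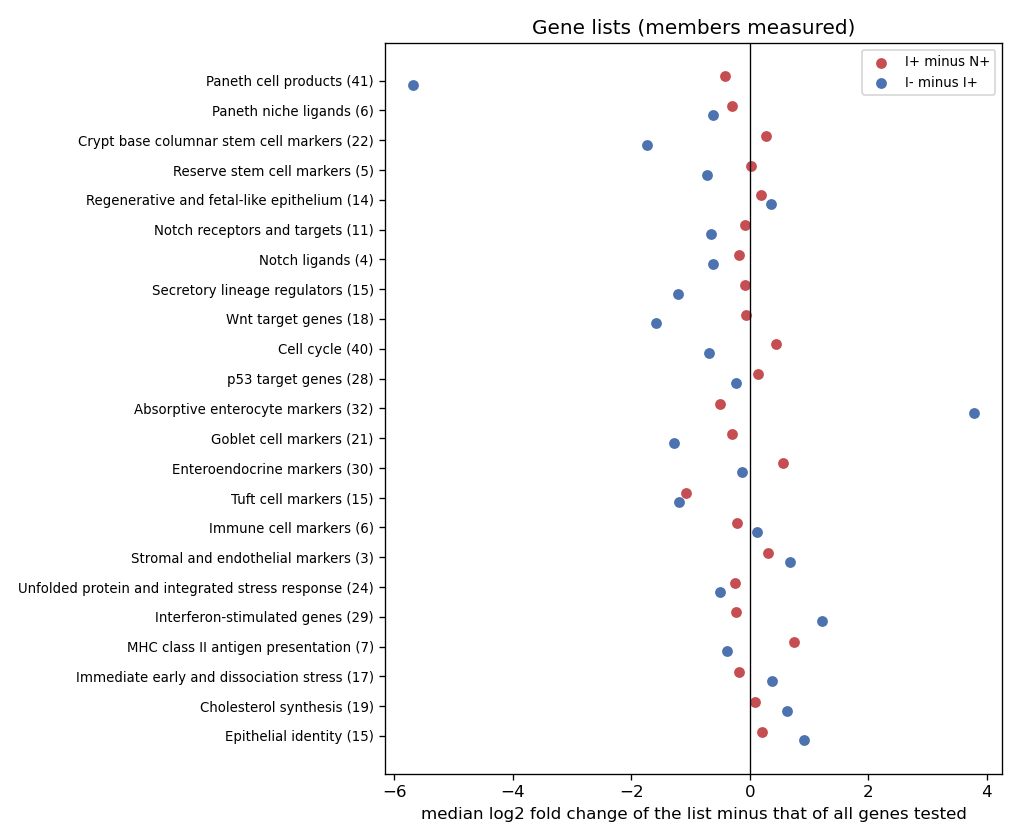
Median log2 fold change of each of the 23 gene lists minus the median of all genes tested (x axis), for irradiated against non-irradiated CD24+ cells (I+ minus N+) and for irradiated CD24− against irradiated CD24+ cells (I− minus I+), with the number of measured members in brackets. Absorptive enterocyte markers lie 3.78 above and Paneth cell products -5.68 from the median gene between the irradiated gates, and tuft markers lie lowest, at -1.08, between the CD24+ groups.

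In total limma with Benjamini-Hochberg adjustment called 6252 of 11190 genes between the irradiated gates, 5439 higher and 813 lower in CD24− cells. After scaling by medians of ratios it called 6350, with 3625 higher and 2725 lower, and 4434 genes were called in both with the same direction and 0 in opposite directions. Quantile normalization called 6229, 2821 higher and 3408 lower, and rescaling to TPM 10260, 10000 higher and 260 lower. The largest rise by the fitted values, Atp6v0c (log2 fold change 7.05 ± 1.01), and the matching fall of its pseudogene copy Atp6v0c-ps2 (-5.66 ± 0.86) share reads and are uncertain: their summed FPKM rose by 1.58 ± 0.29 (adjusted p = 0.000874).

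The third comparison, of irradiated CD24− with non-irradiated CD24+ cells, differs in gate and treatment at once. Lyz1 fell by 5.03 ± 0.80 (SE) on the log2 scale. Of the sort markers Cd24a fell by 3.18 ± 0.42 and Epcam rose by 1.90 ± 0.32. Reg3b, an antibacterial lectin gene, rose from 676 ± 709 (SD, n = 2) to 24331 ± 9212 FPKM (SD, n = 3), St3gal4, a sialyltransferase gene, rose by 5.93 ± 0.61, and Apoa1 by 5.12 ± 0.63. Defa4 fell by 7.25 ± 1.61, Lgr5 by 2.44 ± 0.24, Olfm4 by 1.89 ± 0.75 and Atoh1 by 1.13 ± 0.35. Cdkn1a rose by 2.42 ± 0.41 (adjusted p = 0.000377). Hes1 rose by 1.02 ± 0.35 as deposited (adjusted p = 0.0225), which is 0.14 relative to the median gene. It was not called after scaling by medians of ratios (adjusted p = 0.811), with no filter (0.0711), with quantile normalization (0.905) or without replicate 1 of the non-irradiated group (0.25) or replicate 1 (0.0776) or 2 (0.0601) of CD24− cells. Atoh1 was not called without replicate 2 of the non-irradiated group (adjusted p = 0.110), in TPM (0.695) or with array weights (0.0578). Olfm4 was not called without replicate 1 or 2 of that group (adjusted p = 0.112 and 0.193) or replicate 3 of CD24− cells (0.0602), with no filter (0.128), in TPM (0.534), with array weights (0.305) or with robust empirical Bayes (0.0931). Notch1 (-0.29 ± 0.31), Dll1 (0.32 ± 0.28), Dll4 (-0.26 ± 0.24), Ascl2 (-0.75 ± 0.43) and Mki67 (0.23 ± 0.37) did not pass. Ascl2 passed without replicate 1 of CD24− cells (adjusted p = 0.0164) or with only the 2 groups compared (0.0470), and Notch1, Dll4 and Ascl2 fell after scaling by medians of ratios (0.0212, 0.00109 and 0.0170). In TPM Mki67 (1.497, adjusted p = 0.00176), Dll1 (1.55, 0.000143) and Dll4 (0.99, 0.00348) rose instead. Rescaling to TPM called 10430 genes higher and 212 lower in this comparison, so these rises were shared with most genes. With quantile normalization Mki67 fell (-0.77, adjusted p = 0.0462).

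Limma with Benjamini-Hochberg adjustment called 7907 genes here, 7349 higher and 558 lower, and after scaling by medians of ratios 5781, with 3316 higher and 2465 lower; 3873 were called in both with the same direction and 79 in opposite directions. The camera test called 14 lists, 2 higher and 12 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.201. All 32 enterocyte genes rose, and 13 of 15 tuft, 37 of 41 Paneth, 12 of 22 stem cell and 10 of 18 Wnt target genes fell over all genes, against 13, 37, 7 and 10 adjusted over the list alone. After median-of-ratios scaling 31 enterocyte genes rose, and 13, 38, 19 and 15 of these fell over all genes, with the same counts over the list alone.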

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

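The alternatives that leave out replicate 1 of the non-irradiated or CD24− group or use the replicate block, each together with median-of-ratios scaling, were chosen after seeing the data. Between the CD24+ groups the count of 0 genes became 1 without a filter, 3 with median-of-ratios scaling, 4 with quantile normalization and 5 with only the 2 groups compared. Leaving out single libraries gave 0 to 5185 genes, and 4 without replicate 1 of the non-irradiated group with median-of-ratios scaling. Between the irradiated gates single libraries left out gave 5064 to 5989 genes, leaving out replicate 1 of CD24− cells with median-of-ratios scaling 6134, and TPM 10260. For CD24− against non-irradiated cells the range was 6109 to 8748, and with that scaling 4337 without replicate 1 of the non-irradiated group and 5725 without replicate 1 of CD24− cells. With an estimated correlation 0 lists passed in each comparison. The list counts ranged from 9 to 13, 11 to 15 and 11 to 16 without single libraries.

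Turns are given where the value passed the threshold as deposited or under the alternative. Between the CD24+ groups these lists turned direction: regenerative (0.0254) and interferon (0.907) with median-of-ratios scaling, p53 (0.692), enteroendocrine (0.0479) and interferon (0.0466) without replicate 2 of the non-irradiated group, and Paneth products (0.641) and immune markers (0.641) without replicate 1 with that scaling, all as adjusted p. Without single libraries the adjusted p ranged from 5.63e-05 to 0.692 for p53 targets, 1.74e-14 to 0.0479 for enteroendocrine and 1.26e-26 to 0.0466 for interferon genes. Between the irradiated gates log2 fold changes turned for Dll4 (0.74) and Asns (0.072) in TPM, Maml1 (-0.036) without replicate 1 of CD24− cells with scaling and Hes1 (-0.37) with the block and scaling. With that scaling alone Hes1 had the same value and was not called. For CD24− against non-irradiated cells they turned for Atoh1 (0.15) and Dll4 (0.99) in TPM, Hes1 (-0.046) and Mki67 (-0.77) with quantile normalization, Hes1 (-0.055) without replicate 1 of the non-irradiated group with scaling, and Hes1 (-0.087), Mki67 (-1.03) and Dll1 (-0.79) without replicate 1 of CD24− cells with scaling. The cause of these turns was not tested. Fewer samples and a shift of all genes by the scaling come with these settings, and where both were changed together they cannot be told apart.

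Of 547 alternative values of named genes between the CD24+ groups 514 kept their side of the threshold, 23 of them uncalled with the opposite sign, and 33 became called. Of 1079 between the irradiated gates 1028 kept it (12 uncalled with the opposite sign), 27 lost and 20 gained a call and 4 turned. Of 287 in the last comparison 248 kept it (10 uncalled with the opposite sign), 17 lost and 14 gained a call and 8 turned. Among uncalled list values 32, 6 and 15 had the opposite sign in the 3 comparisons. The replicate block without other scaling changed the calls of Notch1, enteroendocrine markers and cholesterol synthesis genes given above and of no other named gene or list. Low genes rest on few reads, so differences under about 1 FPKM are poorly resolved.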

Other observations

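The tests of gene families, of read numbers and shares of fragments, of splits, of tuft markers and of the Atp6v0c pair were chosen only after the result was seen, unlike the gene counts and the fits without single libraries that they use. Gene families picked after the values were seen add to the account of CD24− against CD24+ cells of irradiated mice. Of 36 subunits of respiratory complex I, the first enzyme of the mitochondrial electron transport chain, 36 rose with and without median-of-ratios scaling by limma with Benjamini-Hochberg adjustment, with a median log2 fold change of 1.60 or 1.09 relative to all genes (camera adjusted p = 3.01e-06, and adjusted p = 0.556 with an estimated correlation). All 15 brush border peptidases and disaccharidases, which finish digestion at the enterocyte surface, rose (median 4.38), as did 7 of 7 bile acid handling genes (median 2.25) and 5 of 5 butyrophilin-like genes (median 3.75), under both scalings. Of 12 UDP-glucuronosyltransferases, which conjugate foreign compounds, 12 rose (11 after scaling). Of 31 cytochrome P450 enzymes 25 rose and 2 fell (23 and 3 after scaling). Members of 1 family, such as the Ugt1a genes, may share reads and are not separate evidence. The butyrophilin-like genes include the pseudogene Btnl5-ps.

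Proteasome subunits rose in 34 of 37 (18 after scaling), whereas of 78 cytosolic ribosomal proteins 1 rose and 0 fell. Of 23 genes of the endoplasmic reticulum translocon and signal peptidase, which admit secreted proteins, 4 rose and 2 fell as deposited, and 0 rose and 16 fell after median-of-ratios scaling. Cd74, the class II invariant chain gene, was highest in replicate 1 of both irradiated gates, at 70.0 FPKM in CD24+ and 118 in CD24− cells. Chga, an enteroendocrine granule gene, was highest in replicate 3 of both, at 246 and 1132 FPKM.

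Most genes called between the irradiated gates were higher in CD24− cells (5439 of 6252), and the median gene was higher by 0.51 on the log2 scale. The log2 ratio of approximated read numbers was -0.050. This ratio cannot weigh a different number of reads as a cause, since FPKM is already scaled to the mapped fragments of each library. Paneth products took so large a share of fragments in CD24+ cells that 46.6% were left for other genes against 98.1% in CD24− cells. The log2 ratio of 1.07 is larger than the shift of 0.51. This share may account for much of the shift but does not match its size, and real changes in total RNA stay open. The shares rest on the 34 of 41 Paneth products with a matched transcript length. For 3 against 3 libraries 10 splits cannot give a share under 0.05: for genes the real split gave 6252 and the highest other 2 (1 split as large), and for lists 14 and 19 (5 splits as large). The other 3 splits that part all 3 same-number pairs, which mix the gates, gave 0, 0 and 0 genes and 15, 9 and 11 lists.

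Tuft markers were lower in irradiated than in non-irradiated CD24+ cells. A single library as the source is argued against, since the list's relative median stayed at -0.93 or below with each library left out. More non-Paneth cells in the non-irradiated gate cannot be told apart from a change of tuft genes. Enteroendocrine genes had a relative median of 0.41 or above, enterocyte (-0.51) and goblet genes (-0.29) a negative one. Enterocyte medians were 13.7 and 61.3 FPKM in the controls against 20.1 to 25.7 in irradiated libraries, goblet medians 36.7 and 74.3 against 70.5 to 151. Neither list fell below both controls in any irradiated library. Tuft medians were 1.75 and 2.95 FPKM in the controls against 1.46, 2.47 and 0.954 in irradiated replicates 1, 2 and 3. By this measure the tuft list fell below both controls in irradiated replicates 1 and 3 but not in replicate 2. Paneth products made up 62.9% and 58.5% of FPKM in the controls against 56.7% to 57.3%. By approximated fragment shares the groups overlapped (69.96% and 54.94% against 51.86% to 56.45%). Fewer tuft cells in the irradiated gate would lower all genes made only by tuft cells by 1 factor. The irradiated to non-irradiated FPKM ratios of the 15 members had a median of 0.412 and a highest value of 1.102. They spread more widely than those of all genes (upper over lower quartile 1.38 against 1.25). The highest ratios were those of Plcg2 (1.102) and Ltc4s (0.709). Both genes were higher in irradiated CD24− than CD24+ cells, so they need not come from tuft cells alone. The spread therefore cannot decide, and this explanation stays open. A shared fall of the programme within tuft cells was not tested and stays open, as does the small number of 2 control libraries.

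Atp6v0c, a proton pump subunit, and its pseudogene copy Atp6v0c-ps2 moved in opposite directions between the irradiated gates. In each of the 8 libraries 1 of the pair held almost all of its summed FPKM, and the lower member held at most 0.782%. Within the non-irradiated group Atp6v0c held 0.504% in replicate 1 and 99.7% in replicate 2. The switch between copies may therefore come from how shared reads were assigned, and no biological explanation was tested. The summed pair was higher in CD24− cells, at 185.0 against 60.8 FPKM (log2 fold change 1.58 ± 0.29, and 1.02 after median-of-ratios scaling, limma adjusted p = 0.000874 and 0.0033).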
